A study of Bos taurus with 20 samples.

How the data were processed

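Neck muscle was collected at a slaughterhouse from 10 cows and stored under vacuum at 4 °C, per the labels. Of these animals, 5 were controls and 5 had received dexamethasone, a synthetic glucocorticoid, by mouth at 0.4 mg per animal per day for 31 days together with intramuscular estradiol, an oestrogen, at 5 mg per animal per week given 6 times. Per its number, each animal gave 1 sample at storage day 0 and 1 at day 14, so that 20 arrays fell into groups of 5 (control and treated, day 0 and day 14). Treatment and day were taken from the sample titles and characteristics. A free-text description field gives day 0 for every control sample and day 14 for every treated sample, which contradicts the titles, and was not used. A treated day 0 sample whose title carries a shortened animal name was read as treated animal DE31 by its number.

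Total RNA was extracted with RNeasy Mini columns and labelled with cyanine 3 for a bovine oligonucleotide array (Agilent design 015354), per the labels' protocols. Per the file headers, signal was extracted with Feature Extraction 9.5.1.1. The main values are the processed signal, a background-subtracted and detrended intensity per spot as deposited by the authors in 1 file per array. The authors also deposited a series table of linear intensity values that are normalized between arrays by a method that neither headers nor labels state. The labels name R 2.11.1 as the authors' software. The processed signal was used because its making is stated, and the series table served as an alternative. Marks that the deposited files set per spot, for outliers and for signal well above background, are other per-spot columns and were used only for filtering.

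Processed signal was transformed to log2 and each array was centred on its 75th percentile, with the mean percentile added back. Spots marked as outliers, 935 over all arrays, were left out, the remaining spots of a probe were averaged, and 1417 control spots were not used. The array holds 42990 other spots for 21475 probes. A probe was tested when it was well above background on at least 5 of the 20 arrays, which left 15438 probes and removed 6037. Of the tested probes, 11411 were well above background on all arrays and 10 had a missing value on some array. Where a probe was not above background in a whole group, its fold change was computed against the background level of that group and is given as "at least". Arrays give no counts, so the number of animals limits the precision of each value.

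Gene names came from the deposited annotation matched to a table of current bovine genes (assembly ARS-UCD2.0), through gene number for 9392 probes, accession for 3442, a symbol in the description for 2903, an older symbol there for 539 and a symbol or synonym for 383. A further 281 probes were left unnamed because their accession and description pointed to different genes. The tested probes carried 11604 distinct symbols on 12584 probes, and 2854 tested probes had none. No gene comes with a genome position here and no genome build was used.

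Groups were compared with limma 3.58.1 (lmFit and eBayes, statmod 1.5.0, data.table version 1.17.8) in R 4.3.3, with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05. Treatment was compared at day 0, at day 14 and over the mean of each animal's arrays. Day 14 was compared with day 0 in control animals, in treated animals and in all animals with treatment as a covariate, and the difference between treatments in that change was tested as an interaction. Errors of log2 fold changes are standard errors (SE) of these fits. Gene lists were tested with limma's camera with a preset correlation of 0.01 on 1 probe per gene (that of highest mean signal), for lists with at least 5 measured genes, with adjustment over the 34 lists of a comparison. Genes with a missing value on an array of the comparison were left out of the list, so that the size of a list can differ between comparisons. Members were counted both by adjusted p over all probes and adjusted over the list alone. Camera with an estimated correlation and fry were run beside it. Measures of array signal were compared with two-sided exact permutation tests, with adjustment over the tests made. Tables and figures were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

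The groups, comparisons, tests, gene lists, named genes and most alternatives were fixed before the data were examined. Genes were named by this rule: in each comparison, the 10 genes with the largest absolute log2 fold change among those that passed and were higher and the 10 among those lower, or all where fewer passed; where none passed, the 3 with the smallest p per direction; the 4 members with the smallest p in the direction of each list that camera called; and a set of glucocorticoid, oestrogen, muscle and meat-tenderness genes named whatever their result. Of that set, PGR was on the array but not tested because of its low signal, and MYH2 was not on the array.

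The labels give the same animal numbers on both days, so the day 0 and day 14 arrays of a number were taken to come from 1 animal. The correlation of their deviations from the group means was checked and ranged from -0.15 (treated animal DE27) to 0.28 (treated animal DE29), and the arrays of 5 of the 10 animals correlated best with their own number. The storage comparisons were fitted without the animal, and the animal as a replicate block was an alternative. The arrays lie on 6 slides, per the file headers. The arrays whose signal was extracted on the same date are called a scan session here, which gives 3 sessions. The header field used dates the extraction and not the scan itself. Only slide 6 holds both days of control animals. Only slide 5 holds both days of treated animals, with both arrays of DE32. Slides 1 to 3 form 1 run of serial numbers and slides 4 to 6 another, called slide set 1 and slide set 2. Signs and medians within slides, sessions or slide sets are given for probes called over the same arrays, so that the choice of probes favours their keeping the sign. Alternatives were other scalings (median centring, quantile normalization, values of the series table), normexp background correction with an offset of 50, no filter and a stricter filter, array weights, an intensity trend, a threshold of 0.1, blocks for slide, slide set, scan session and animal, and leaving out each animal in turn.

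The scripts were tested on simulated data with 15428 probes, of which 100 were changed at each fold size. Of probes changed 4-fold, the share recovered was 88% for treatment at day 0, 89% at day 14, 94% over both days, 85% for storage in control animals, 87% in treated animals, 97% in all animals and 63% for the interaction. Of probes changed 2-fold, it was 28%, 30%, 62%, 36%, 31%, 67% and 21% in the same order. Of 30 simulated lists of 25 members, camera called the 1 that was shifted by 0.5 and none of the others. Simulated genes were drawn independently of each other, so this says nothing about false calls of lists whose members are correlated.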

Results

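Gene expression was measured in bovine neck muscle from 5 control cows and 5 cows given dexamethasone with estradiol, at day 0 and after 14 days of vacuum storage at 4 °C. The design asks which transcripts separate treated from control animals, whether these differences are still measured after storage, and what storage does to the transcripts in muscle. Each of the 4 groups holds 5 arrays, and each array is 1 sample of 1 animal. Arrays of the same group correlated with each other across probes with r between 0.945 and 0.986.

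Array signal was lower after storage in both treatments. The 75th percentile of the processed signal was 806 ± 114 (SD, n = 5) in control and 821 ± 99.0 in treated animals at day 0, and 428 ± 99.0 and 377 ± 53.1 at day 14. On the log2 scale it fell by 1.03 within animals, in 10 of 10 animals (exact permutation p = 0.00195, adjusted p = 0.00977). The share of spots well above background was 66.1% ± 3.36 in control and 66.2% ± 1.43 in treated animals at day 0, and 62.2% ± 3.80 and 61.9% ± 3.31 at day 14. It was lower in 8 of 10 animals (exact permutation p = 0.0215, adjusted p = 0.0806). Within an array, the median signal lay closer to the 75th percentile at day 14, by 0.31 on the log2 scale in 10 of 10 animals (exact permutation p = 0.00195, adjusted p = 0.00977). Between treatments, no measure of array signal differed at either day (exact permutation p from 0.357 to 1).

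**Figure D1:**
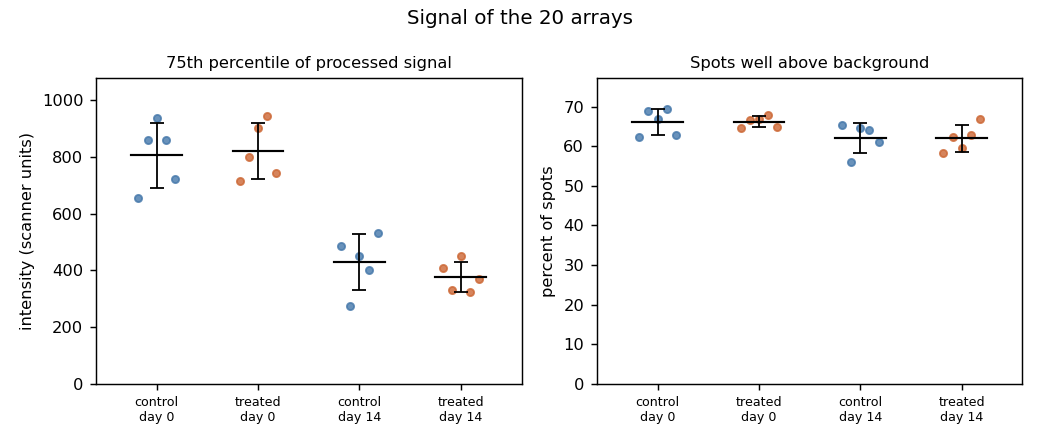
Left, 75th percentile of the processed signal (linear intensity) of each array; right, percent of spots well above background; points are arrays, lines are group means and bars are SD (n = 5 per group). The 75th percentile lies between 654 and 945 at day 0 and between 274 and 533 at day 14.

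At day 0, single genes of several kinds differed between treated and control muscle. CCL2, a chemokine that attracts monocytes, was 11-fold higher in treated animals (log2 fold change 3.46 ± 0.58 SE, n = 5 per group, adjusted p = 0.0161). DGAT2, which completes triglyceride synthesis, was 7.46-fold higher (2.90 ± 0.28, adjusted p = 0.00153). The interferon-induced genes IFIT3, at least 6.97-fold higher (2.80 ± 0.33), GBP6, 7.07-fold higher (2.82 ± 0.48), and IDO1, a tryptophan-degrading enzyme and 5.14-fold higher (2.36 ± 0.36), rose with them. PER1, a clock gene that glucocorticoids induce, was 7.43-fold lower (-2.89 ± 0.20, adjusted p = 0.000301). CYP1A1, a monooxygenase induced through the aryl hydrocarbon receptor, was 13.9-fold lower (-3.79 ± 0.63). RGS1, a regulator of G-protein signalling, was 9.84-fold lower (-3.30 ± 0.46), and HES6, a transcription factor, was at least 11.4-fold lower (-3.51 ± 0.41).

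**Figure D2:**
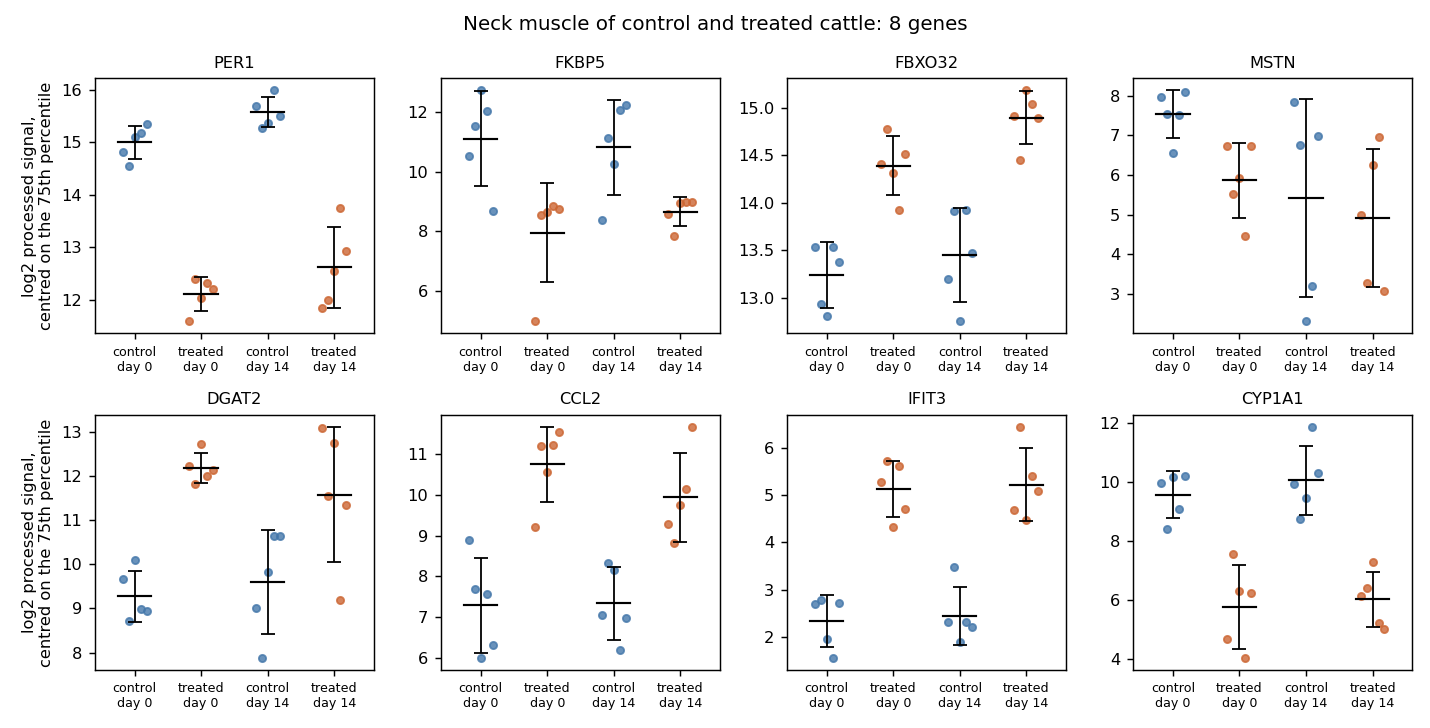
Log2 processed signal, centred on the 75th percentile, of 8 genes in control and treated animals at day 0 and day 14; points are arrays, lines are means and bars are SD (n = 5 per group). PER1 averages 15.0 in control and 12.11 in treated animals at day 0, and 15.57 and 12.62 at day 14.

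Among the muscle and hormone genes named in advance, FBXO32, which encodes a ubiquitin ligase of muscle wasting, rose 2.22-fold at day 0 (1.15 ± 0.21, adjusted p = 0.0188). FKBP5, a co-chaperone of the glucocorticoid receptor, had a value of -3.16 ± 0.89 that did not pass (adjusted p = 0.0915) but passed with the slide as a block (-3.31, adjusted p = 0.00619, over all alternatives 0.00267 to 0.205). Without treated animal DE27 its value was -2.41 (adjusted p = 0.108). MSTN, the growth inhibitor myostatin, had -1.66 ± 0.44 (adjusted p = 0.0782, 0.0349 with the slide as a block), and KLF15 -1.06 ± 0.58 (adjusted p = 0.391, 0.0394 with that block). The ubiquitin ligase TRIM63 (-0.19 ± 0.26), the glucocorticoid receptor NR3C1 (0.07 ± 0.19), the oestrogen receptor ESR1 (-0.66 ± 0.22), PDK4 (0.16 ± 0.80), TSC22D3 (-0.59 ± 0.26) and KLF9 (-0.50 ± 0.18) did not pass. Neither did IGF1 (0.36 ± 0.20), HSD11B1 (0.39 ± 0.38), COL1A1 (0.06 ± 0.40), MYH7 (-0.17 ± 0.12), FABP4 (0.45 ± 0.84) or SCD (0.53 ± 0.25).

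Fatty acid oxidation genes were higher as a group at day 0 (median log2 fold change 0.51 over 26 genes, 24 above 0). This was the only list of the comparison that camera also called with an estimated correlation (adjusted p = 1.88e-09, and 0.0273 with an estimated correlation). Of its members 5 rose over all probes and 14 when adjusted over the list alone, among them ECI1, an enoyl-CoA isomerase (0.75 ± 0.13). Interferon-stimulated genes had a median of 1.01 over 19 genes, with 2 that rose over all probes and 10 adjusted over the list alone, IFIT3 and GBP4 (1.71 ± 0.29) among them. Camera called interferon-stimulated genes (adjusted p = 3.78e-09, adjusted p = 0.204 with an estimated correlation). Glucocorticoid-induced genes had a median of -0.64 over 26 genes, with 5 that fell and 1 that rose over all probes, and 12 and 2 adjusted over the list alone. Camera called glucocorticoid-induced genes (adjusted p = 1.12e-06, adjusted p = 0.204 with an estimated correlation). Beside PER1, the members that fell were NFKBIA, the inhibitor of NF-kB (-1.47 ± 0.23), SESN1 (-1.42 ± 0.24), PIK3R1, a regulatory subunit of PI3-kinase (-1.25 ± 0.22), and CEBPB (-1.10 ± 0.23). The member that rose was IRS2 (1.01 ± 0.23). The last 2 were named after their values were seen.

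Oxidative phosphorylation genes lay above 0 for 43 of 53 genes at day 0 (median 0.24, 2 rose over all probes and 5 adjusted over the list alone, camera adjusted p = 2.09e-06, adjusted p = 0.486 with an estimated correlation). Ribosomal protein genes lay below 0 for 62 of 68, with none past the threshold either way of counting (median -0.20, camera adjusted p = 1.11e-05, adjusted p = 0.454 with an estimated correlation). Of the adipocyte and lipogenic genes, 2 of 29 rose over all probes and 3 adjusted over the list alone, DGAT2 and CIDEA, a lipid droplet protein (0.94 ± 0.16), among them. Camera called adipocyte and lipogenic genes (adjusted p = 0.00268, adjusted p = 0.225 with an estimated correlation). Antigen presentation genes had 3 that rose over all probes, the immunoproteasome subunits PSMB9 (1.27 ± 0.16) and PSMB8 (0.90 ± 0.14) and BOLA-DMB (0.76 ± 0.15), and 4 higher and 1 lower adjusted over the list alone (21 genes, camera adjusted p = 0.0099, adjusted p = 0.225 with an estimated correlation). Antioxidant and metallothionein genes had 4 that rose over all probes, MT3 (1.55 ± 0.28), HMOX1 (1.25 ± 0.25), GPX1 (0.74 ± 0.17) and PRDX2 (0.78 ± 0.18), and 4 higher and 1 lower adjusted over the list alone (27 genes). Camera called antioxidant and metallothionein genes (adjusted p = 0.0144, adjusted p = 0.204 with an estimated correlation).

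Of the marker lists of other cell types, camera called 3 at day 0, each with few members that passed and none with an estimated correlation. Endothelial markers were above 0 for 16 of 19 genes, with 1 that rose by either count, the fatty acid carrier FABP5 (1.62 ± 0.15; camera adjusted p = 0.00267, adjusted p = 0.204 with an estimated correlation). Satellite cell and myogenic genes were below 0 for 17 of 21, with 2 that fell over all probes and 4 adjusted over the list alone, CHRNG, the fetal subunit of the acetylcholine receptor (-2.03 ± 0.31), and the cadherin CDH15 (-0.70 ± 0.16) among them. Camera called satellite cell and myogenic genes (adjusted p = 0.00273, adjusted p = 0.204 with an estimated correlation). Nerve and Schwann cell markers were below 0 for 12 of 13, with 0 that passed over all probes and 4 lower adjusted over the list alone. Camera called nerve and Schwann cell markers (adjusted p = 0.0122, adjusted p = 0.39 with an estimated correlation). Without control animal K9 or treated animal DE29 the nerve list was not called (adjusted p = 0.0508 and 0.0644).

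In limma, 203 probes (160 genes) were higher and 175 (132 genes) lower in treated animals at day 0, 113 and 106 of them by at least 2-fold. The count was 210 without control animal K8, 135 without K9, 228 without K10, 177 without treated animal DE29, 222 without DE31 and 250 without DE32. Of 42 named genes that passed, 23 passed without each animal in turn. Without K9, the adjusted p was 0.0514 for DPP6 (-3.94 ± 0.68), 0.0544 for GDF10 (-2.98 ± 0.54), 0.0544 for MT3 and 0.0533 for PIK3R1. The other 15 lost their call without several animals, HMOX1, GPX1, PRDX2, BOLA-DMB and CDH15 among them (without K9, 0.0746, 0.121, 0.127, 0.0738 and 0.122). Within slides 1, 3 and 6, the slides that hold both treatments at day 0, all 378 called probes kept their sign. Their medians in the called direction were 1.0, 1.12 and 1.19 against 1.07 over all arrays. List medians kept their sign in every scan session, and in both slide sets except for the adipocyte list (-0.15 in slide set 2).

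After 14 days of storage, differences between treated and control muscle were measured for 8 named genes. CYP1A1 was 16.3-fold lower in treated animals (-4.03 ± 0.57, n = 5 per group), RGS1 12.6-fold lower (-3.66 ± 0.43), PER1 7.74-fold lower (-2.95 ± 0.34) and HES6 6.75-fold lower (-2.75 ± 0.41). IFIT3 was at least 5.93-fold higher (2.79 ± 0.39), the bicarbonate transporter SLC4A4 at least 3.15-fold (1.88 ± 0.28), the tryptophan tRNA synthetase WARS1 2.80-fold (1.49 ± 0.21) and the early response gene IER3 2.45-fold (1.29 ± 0.19). Their limma adjusted p was 0.0217 for RGS1 and PER1 and 0.0355 for the others. FBXO32 (1.45 ± 0.25, adjusted p = 0.0821), NFKBIA (-1.64 ± 0.28, adjusted p = 0.0795), GBP4 (2.07 ± 0.37, adjusted p = 0.0821) and FKBP5 (-2.15 ± 0.63, adjusted p = 0.294) did not pass. MSTN had -0.51 ± 1.14 (adjusted p = 0.897). Its day 14 signal was not well above background in control animals K8 and K9 (2.3 and 3.185) and treated animals DE29 and DE32 (3.277 and 3.069), so this value does not show that a difference was absent.

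Lists that camera called at day 14 all lost the call with an estimated correlation (adjusted p = 0.82, and 0.832 for proteasome subunits), and fry called 0 lists. Fibroblast and extracellular matrix genes were below 0 for 31 of 33, with a median of -0.75 and 0 members past the threshold by either count (camera adjusted p = 2.25e-09, adjusted p = 0.82 with an estimated correlation). The median was -2.22 in scan session 1 and -0.02 in session 2. Session 1 holds 1 control array at day 14, that of K6, whose 75th percentile (274) was the lowest of all arrays. Interferon-stimulated genes had a median of 0.77, with 1 that rose over all probes, IFIT3, and 5 adjusted over the list alone (camera adjusted p = 6.25e-08). Glucocorticoid-induced genes had a median of -0.56, with 1 that fell over all probes, PER1, and 8 lower and 1 higher adjusted over the list alone (camera adjusted p = 8.43e-07). Oxidative phosphorylation genes were above 0 for 50 of 52 (median 0.33, camera adjusted p = 4.61e-05), and fatty acid oxidation genes for 26 of 26 (median 0.42, camera adjusted p = 0.000333), with 0 members past the threshold by either count in both lists. The latter had an adjusted p of 0.053 without control animal K6 and a median of -0.02 in scan session 2, and oxidative phosphorylation genes had 1.14 in session 1, 0.12 in session 2 and -0.76 in slide 5. Smooth muscle and pericyte markers (median -0.46, camera adjusted p = 0.000757) and nerve and Schwann cell markers (median -0.61, camera adjusted p = 0.000757) had 0 members that passed over all probes and 1 lower adjusted over the list alone. The smooth muscle median was -1.40 in session 1, -0.16 in session 2 and 1.17 in slide 5, which holds 1 array of each treatment, and there the medians of the fibroblast (0.53), fatty acid oxidation (-0.40) and nerve (0.37) lists were also of opposite sign. Antigen presentation genes had a median of 0.33 (camera adjusted p = 0.00152) and 0 members past the threshold.

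The remaining lists called at day 14 lost the call without single animals and under other settings. The call of lymphocyte markers (median -0.34, adjusted p = 0.00939) ended without K9 (0.109) and DE30 (0.0604) and after normexp correction (0.536). That of mitochondrially encoded genes (0.38, adjusted p = 0.00991) ended without K3, K10, DE29 and DE32 (0.0595, 0.0726, 0.0671 and 0.0544), after quantile normalization (0.392) and with the slide as a block (0.136). That of proteasome subunits (0.22, adjusted p = 0.0102) ended without K6, K9, DE27 and DE30 (0.161, 0.192, 0.174 and 0.109) and after normexp correction (0.0981). For glycolysis genes (0.36, adjusted p = 0.032) it ended without K8, K9, DE27, DE30 and DE31 (0.0725, 0.262, 0.123, 0.0932 and 0.125), after quantile normalization (0.184) and with the slide set as a block (0.0532). For fast-fibre genes (0.28, adjusted p = 0.036, median -0.20 in scan session 1) it ended without the same 5 animals (0.238, 0.262, 0.104, 0.0932 and 0.318), after quantile normalization (0.208) and normexp correction (0.132), with the slide (0.16) and the slide set (0.0532) as a block, and with the mean of a gene's probes. For immediate early genes (-0.09, adjusted p = 0.0375) it ended without K8, K9, DE27 and DE29 (0.197, 0.0526, 0.673 and 0.0671), after quantile normalization (0.0656) and with the slide (0.122) and the slide set (0.168) as a block. The median of these genes was 0.02 after normexp background correction and 0.15 in scan session 2. These 6 lists had 0 members that passed over all probes, except for IER3 in the immediate early list, which also had 2 higher and 4 lower adjusted over the list alone.

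Limma called 4 probes (4 genes) higher and 7 (4 genes) lower at day 14, with 1613 at an unadjusted p under 0.05. With the slide as a block 0 were called (970 at an unadjusted p under 0.05; the adjusted p of the named genes was 0.103 to 0.289). With all arrays and the animal as a random replicate block 110 were called. The count was 0 without any 1 of control animals K3, K8, K9 and K10 or of treated animals DE29 and DE30, and 2 without DE27. All 11 called probes had the same sign in both scan sessions and in slides 2, 4 and 5, with medians in the called direction of 2.46, 2.64 and 2.23 against 2.79 over all arrays.

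Over the mean of each animal's days, which holds the day 0 arrays too, CYP1A1 was 15.1-fold lower in treated animals (-3.91 ± 0.47, n = 5 per group, adjusted p = 0.00304), PER1 7.58-fold lower (-2.92 ± 0.22, adjusted p = 0.00046) and FKBP5 6.30-fold lower (-2.65 ± 0.52, adjusted p = 0.0218). The Wnt inhibitor DKK1 (-2.0 ± 0.27), CHRNG (-2.01 ± 0.32) and the stress gene GADD45G (-2.41 ± 0.44) fell with them. CCL2 was 8.18-fold higher (3.03 ± 0.41, adjusted p = 0.00368), DGAT2 5.42-fold (2.44 ± 0.42), IDO1 4.98-fold (2.32 ± 0.30), METTL21E, a methyltransferase of skeletal muscle, 3.74-fold (1.90 ± 0.20) and FBXO32 2.46-fold (1.30 ± 0.16, adjusted p = 0.00311). MSTN had -1.09 ± 0.63, with day 14 signal not well above background in K8, K9, DE29 and DE32, and ESR1 had -0.66 ± 0.20. Neither passed.

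Over both days, 7 of 19 interferon-stimulated genes rose over all probes and 12 adjusted over the list alone, ISG15 (1.41 ± 0.32) and HERC6 (1.22 ± 0.19) among them (median 0.89). Camera called interferon-stimulated genes (adjusted p = 9.94e-09, adjusted p = 0.518 with an estimated correlation). Of 26 glucocorticoid-induced genes, 7 fell over all probes, and 12 were lower and 1 higher adjusted over the list alone, PER1, FKBP5, NFKBIA (-1.56 ± 0.21), PIK3R1 (-1.11 ± 0.15) and the cell cycle inhibitor CDKN1A (-1.08 ± 0.19) among them (median -0.60). Camera called glucocorticoid-induced genes (adjusted p = 9.24e-08, adjusted p = 0.518 with an estimated correlation). Fatty acid oxidation genes had 2 that rose over all probes, ACSL1 (0.91 ± 0.18) and ETFDH (1.26 ± 0.28), and 13 adjusted over the list alone (median 0.48). Camera called fatty acid oxidation genes (adjusted p = 1.8e-08, adjusted p = 0.518 with an estimated correlation). Oxidative phosphorylation genes were above 0 for 53 of 54, with 0 that passed (camera adjusted p = 9.24e-08, adjusted p = 0.593 with an estimated correlation). Fibroblast and extracellular matrix genes had 2 that fell over all probes, MMP2 (-0.51 ± 0.12) and COL5A2 (-0.58 ± 0.14), and 5 adjusted over the list alone (median -0.26, 0.64 in scan session 3 and 0.09 in slide set 2; camera adjusted p = 8.96e-05, adjusted p = 0.518 with an estimated correlation). Nerve and Schwann cell markers (2 that fell over all probes, 4 adjusted over the list alone, PMP22 at -1.06 ± 0.23), antigen presentation genes (1 that rose, PSMB9 at 1.04 ± 0.18, and 5) and antioxidant and metallothionein genes (3 that rose and 5) had camera adjusted p of 0.00117, 0.00189 and 0.0135 (0.518 with an estimated correlation for each). Ribosomal protein genes (0 that passed, camera adjusted p = 0.0168, adjusted p = 0.665 with an estimated correlation) were not called without K3 (0.101) or DE27 (0.114). Satellite cell and myogenic genes (1 and 2 that fell, camera adjusted p = 0.0335, adjusted p = 0.518 with an estimated correlation) were not called without K6, K8, K10 and DE29 (0.0579, 0.0552, 0.103 and 0.11) or with the mean of a gene's probes.

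Limma called 213 probes (162 genes) higher and 298 (228 genes) lower in treated animals over both days. The count was 932 with all arrays and the animal as a random replicate block. It was 234 without control animal K8, 215 without K9, 312 without K10, 314 without treated animal DE27, 256 without DE29 and 294 without DE30. Of 37 named genes that passed, 25 did so without each animal in turn. FKBP5 was not called without K8, K9 or DE29 (adjusted p = 0.055, 0.053 and 0.0508). ACSL1, ETFDH, ISG15, MMP2, COL5A2 and PMP22 were not called without several animals (without K9, adjusted p = 0.0685, 0.0926, 0.0953, 0.097, 0.0882 and 0.0708).

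Of the probes called at day 0, 9 were also called in the same direction at day 14, 3 higher and 6 lower, where independent lists would share 0.0526 and 0.0793. The genes among them include PER1, CYP1A1, RGS1, HES6 and IFIT3. At day 14, 199 of the 203 probes higher at day 0 and 167 of the 175 lower ones had the same sign. Across all probes, which are not independent replicates, the log2 fold changes of the days correlated with Pearson's r = 0.523 and Spearman's rho = 0.417, and both days come from the same animals. The shared count was 0 without any 1 of K3, K8, K9, K10, DE29 and DE30, 2 without DE27 and 4 without DE32.

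Many muscle transcripts differed between day 0 and day 14 of storage in control animals. Values are centred on the 75th percentile of each array, which fell by 1.03 on the log2 scale with storage. Higher, lower, rose and fell with storage are therefore relative to the other probes of an array. They do not give the amount of a transcript left in the muscle. TTN, which encodes the giant sarcomere protein titin, was 7.90-fold higher at day 14 (2.98 ± 0.47, n = 5 per day, adjusted p = 0.00126). So were the nuclear receptor gene NR4A3 (8.22-fold, 3.04 ± 0.55) and EXT1, an enzyme of heparan sulphate synthesis (6.69-fold, 2.74 ± 0.38). PDLIM3, a protein of the Z-disc, was 9.32-fold lower (-3.22 ± 0.53, adjusted p = 0.00155) and the ubiquitin-conjugating enzyme UBE2D1 6.52-fold lower (-2.70 ± 0.42). CAST, which encodes the calpain inhibitor calpastatin, was 1.72-fold lower (-0.78 ± 0.21, adjusted p = 0.0142) and ACTB 1.68-fold higher (0.75 ± 0.20, adjusted p = 0.0121). The proteases CAPN1 (0.14 ± 0.15), CAPN2 (0.09 ± 0.22), CTSB (-0.14 ± 0.16) and CTSD (0.27 ± 0.14) did not pass. Nor did GAPDH (-0.26 ± 0.22), FOS (-0.19 ± 0.50) or the heat shock genes HSPA1A (-0.24 ± 0.24), HSPB1 (0.05 ± 0.28) and CRYAB (0.21 ± 0.38).

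The counts of list members in control animals stand beside 3370 higher and 2675 lower of all 15438 probes tested. Proteasome genes were lower as a group at day 14 in control animals, with 20 of 31 that fell and 1 that rose over all probes, and 22 and 1 adjusted over the list alone, PSMA1 (-1.49 ± 0.27) and PSMD14 (-1.49 ± 0.28) among them. Camera called proteasome genes (adjusted p = 1.62e-05, adjusted p = 0.649 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes had 24 of 53 that fell by either count, ATP5PB (-1.97 ± 0.43) and NDUFB5 (-1.35 ± 0.28) among them. Camera called oxidative phosphorylation genes (adjusted p = 7.7e-05, 0.521 with the slide as a block, adjusted p = 0.654 with an estimated correlation). Genes encoded by the mitochondrial genome had 8 of 13 that rose over all probes and 10 adjusted over the list alone, COX1 (1.22 ± 0.30) among them. Camera called mitochondrially encoded genes (adjusted p = 0.00389, 0.246 after normexp correction, adjusted p = 0.649 with an estimated correlation). Endothelial markers had 12 of 19 that rose and 14 adjusted over the list alone, ENG (1.31 ± 0.25) among them (camera adjusted p = 7.7e-05, adjusted p = 0.649 with an estimated correlation). Smooth muscle and pericyte markers had 10 of 15 and 11, MYH11 (1.92 ± 0.52) and TAGLN (1.31 ± 0.34) among them (camera adjusted p = 0.00148, adjusted p = 0.649 with an estimated correlation). Ribosomal protein genes had 17 of 66 that fell over all probes and 9 adjusted over the list alone, RPS26 (-1.55 ± 0.21) among them. Camera called ribosomal protein genes (adjusted p = 0.000249, 0.137 after quantile normalization, 0.072 with the slide as a block, adjusted p = 0.649 with an estimated correlation). Muscle atrophy genes had 9 of 20 that fell and 1 that rose, and 10 and 1 adjusted over the list alone, the ubiquitin gene UBB (-1.37 ± 0.20) and the autophagy gene MAP1LC3B (-1.85 ± 0.27) among them. Camera called muscle atrophy genes (adjusted p = 0.0203, 0.0848 after quantile normalization, adjusted p = 0.649 with an estimated correlation). Glycolysis and glycogen genes had 10 of 26 that fell by either count, UGP2 (-1.75 ± 0.23) and PGK1 (-1.65 ± 0.34) among them. Camera called glycolysis and glycogen genes (adjusted p = 0.0176, 0.109 with the slide as a block, 0.119 with the slide set as a block, adjusted p = 0.649 with an estimated correlation). Interferon-stimulated genes had 7 of 19 that rose and 1 that fell by either count, RSAD2 (1.43 ± 0.26) among them. Camera called interferon-stimulated genes (adjusted p = 0.0126, 0.0526 without control animal K10, adjusted p = 0.649 with an estimated correlation).

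In control animals limma called 3370 probes (2364 genes) higher and 2675 (2281 genes) lower at day 14, which is 39.2% of the probes tested. The count was 183 with the slide as a block, 0 with the animal as a replicate block together with the slide set (3477 at an unadjusted p under 0.05) and 3214 without control animal K9. Of 58 named genes that passed, 48 passed without each animal in turn. CAST was not called without K3 (adjusted p = 0.0503) or K8 (0.068), ACTB without K8 (0.0507) or K9 (0.0557), MYH11 without K6 (0.0587) or K9 (0.0643), and TAGLN without K6 (0.0535), K8 (0.0507) or K9 (0.0515). Within slide set 1, slide set 2 and slide 6, the only slide with both days, 99.4%, 99.0% and 98.7% of the called probes kept their sign. Medians in the called direction were 1.13, 0.85 and 0.85 against 0.96 over all arrays.

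In treated animals TTN was 8.03-fold higher at day 14 (3.01 ± 0.27, n = 5 per day, adjusted p = 0.000135), the synaptic scaffold gene DLGAP1 9.02-fold (3.17 ± 0.36) and the Wnt co-receptor gene LRP4 7.50-fold (2.91 ± 0.28). PDLIM3 was 8.26-fold lower (-3.04 ± 0.56, adjusted p = 0.00298) and the mitochondrial glutaredoxin GLRX2 6.01-fold lower (-2.59 ± 0.23, adjusted p = 0.000135). CIDEC, a lipid droplet protein, was 10.5-fold lower (-3.39 ± 0.88, adjusted p = 0.0149, 0.0809 without treated animal DE31). CAST was 1.43-fold lower (-0.52 ± 0.18, adjusted p = 0.045) and lost its call with the animal as a replicate block (adjusted p = 0.0598) and without any 1 treated animal (adjusted p from 0.0539 without DE27 to 0.143 without DE29). CAPN1 (0.14 ± 0.15), CAPN2 (-0.12 ± 0.17), CTSB (-0.26 ± 0.14), CTSD (0.24 ± 0.14), HSPA1A (-0.04 ± 0.50), HSPB1 (0.09 ± 0.21), CRYAB (0.39 ± 0.43), FOS (-0.29 ± 0.65), ACTB (0.49 ± 0.30) and GAPDH (0.35 ± 0.20) did not pass.

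Counts of list members in treated animals stand beside 2802 higher and 1784 lower of all 15438 probes tested. In treated animals, 7 of 13 mitochondrially encoded genes rose over all probes and 12 adjusted over the list alone, COX3 (1.04 ± 0.18) among them. Camera called mitochondrially encoded genes (adjusted p = 0.000278, 0.161 after normexp correction, adjusted p = 0.822 with an estimated correlation, the value for each list that follows). Fry called this list and none of those that follow. Of 31 proteasome genes, 11 fell and 1 rose, and 13 and 1 adjusted over the list alone, PSMD14 at -1.42 ± 0.24 (camera adjusted p = 0.000759). Of 52 oxidative phosphorylation genes 13 fell by either count, NDUFB5 at -1.42 ± 0.30 (camera adjusted p = 0.000759). Of 19 endothelial markers 8 rose over all probes and 9 adjusted over the list alone, EGFL7 at 0.98 ± 0.25 (camera adjusted p = 0.000972, 0.203 after normexp correction). Fibroblast and extracellular matrix genes had 6 of 33 that fell over all probes and 2 adjusted over the list alone, LUM (-2.15 ± 0.50) and DCN (-1.41 ± 0.42) among them. Their median of -0.63 was 0.04 in scan session 2. It was 0.57 with the slide as a block, which in treated animals compares the days through 1 animal, DE32, on slide 5. Camera called the list (adjusted p = 0.00351), but not without treated animal DE27 (0.219) or with the slide as a block (0.0601). Fatty acid oxidation genes had 5 of 26 that fell and 4 adjusted over the list alone, ETFDH at -1.74 ± 0.46 (camera adjusted p = 0.0345, 0.15 after quantile normalization, 0.182 without DE31 and 0.109 without DE32). Antioxidant genes had 5 of 27 that fell and 1 that rose by either count, SOD1 at -1.29 ± 0.24 (camera adjusted p = 0.0435, 0.171 after quantile normalization, 0.121 with the slide and 0.0583 with the slide set as a block, 0.141 without DE31). Interferon-stimulated genes had 4 of 19 that rose by either count, HERC6 at 1.76 ± 0.33 (camera adjusted p = 0.0435, 0.0611 after normexp correction, 0.132 without DE29 and 0.112 without DE32). Muscle atrophy genes had 5 of 20 that fell and 1 that rose by either count, UBB at -1.37 ± 0.21 (camera adjusted p = 0.0487, 0.15 after quantile normalization, 0.0675 without DE27, 0.134 without DE29 and 0.109 without DE32). That list was not called with the mean of a gene's probes either.

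Limma called 2802 probes (1873 genes) higher and 1784 (1579 genes) lower at day 14 in treated animals, 29.7% of those tested. The count was 0 with the slide as a block (3042 at an unadjusted p under 0.05), 2664 without DE29, 2501 without DE31 and 2441 without DE32. Of 57 named genes that passed, 33 did so without each animal in turn. Without DE29 the adjusted p was 0.111 for DCN, 0.0553 for LUM and 0.0831 for ETFDH. All 4586 called probes kept their sign in both slide sets, with medians in the called direction of 1.04 and 1.02 against 1.04 over all arrays, and 99.3% did so in slide 5, the only slide with both days. Slide 5 holds 1 treated array per day, both of DE32. The slide as a block therefore compares the days of treated animals through DE32 alone.

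Over all animals TTN was 7.96-fold higher at day 14 (2.99 ± 0.28, n = 10 per day, adjusted p = 6.43e-08) and PDLIM3 8.77-fold lower (-3.13 ± 0.40, adjusted p = 3.2e-06). GLRX2 was 5.35-fold lower (-2.42 ± 0.18, adjusted p = 5.58e-09) and CAST 1.57-fold lower (-0.65 ± 0.13, adjusted p = 0.000393, 0.0784 with the slide as a block). ACTB was 1.54-fold higher (0.62 ± 0.18, adjusted p = 0.00686, 0.108 with the slide as a block), and CTSD, a lysosomal protease, had 0.25 ± 0.08 (adjusted p = 0.014, 0.637 with the slide as a block and 0.966 after normexp correction). CAPN1 (0.14 ± 0.09), CAPN2 (-0.02 ± 0.14), CTSB (-0.20 ± 0.09), GAPDH (0.04 ± 0.16, -0.35 after quantile normalization, with another probe of the gene called in the opposite direction), HSPA1A (-0.14 ± 0.29), HSPB1 (0.07 ± 0.17), CRYAB (0.30 ± 0.30) and FOS (-0.24 ± 0.43) did not pass.

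**Figure D3:**
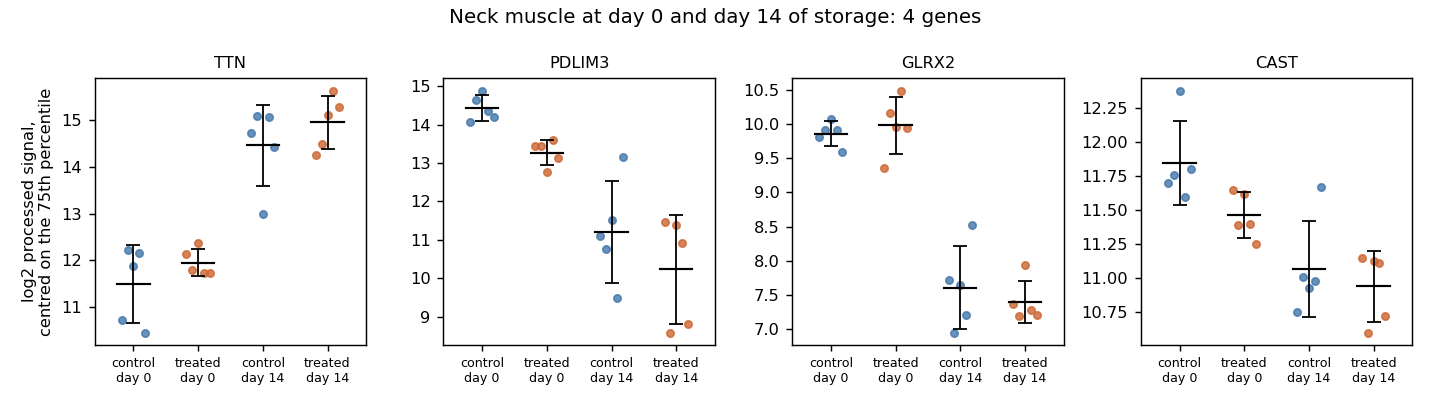
Log2 processed signal, centred on the 75th percentile, of TTN, PDLIM3, GLRX2 and CAST at day 0 and day 14 in control and treated animals; points are arrays, lines are means and bars are SD (n = 5 per group). TTN averages 11.49 and 14.47 in control and 11.95 and 14.96 in treated animals at day 0 and day 14.

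Counts of list members over all animals stand beside 4873 higher and 3562 lower of all 15438 probes tested. Over all animals, 20 of 31 proteasome genes fell and 1 rose, and 22 and 1 adjusted over the list alone, PSMA5 at -1.09 ± 0.14. Camera called proteasome genes (adjusted p = 5.92e-05, adjusted p = 0.773 with an estimated correlation). Of 51 oxidative phosphorylation genes 26 fell and 1 rose, and 29 and 1 adjusted over the list alone, COX5A at -1.47 ± 0.27 (camera adjusted p = 0.000221, 0.246 with the slide as a block, adjusted p = 0.844 with an estimated correlation). By contrast, 12 of 13 mitochondrially encoded genes rose by either count, COX3 at 0.82 ± 0.13. Camera called mitochondrially encoded genes (adjusted p = 0.000404, 0.168 after normexp correction, adjusted p = 0.773 with an estimated correlation). Endothelial markers had 16 of 19 that rose and 17 adjusted over the list alone, ENG at 1.19 ± 0.19 (camera adjusted p = 0.000221). Smooth muscle and pericyte markers had 11 of 15 by either count, TAGLN at 0.90 ± 0.25 (camera adjusted p = 0.0234, 0.215 after normexp correction). Interferon-stimulated genes had 11 that rose and 1 that fell of 19, and 12 and 1 adjusted over the list alone, HERC6 at 1.71 ± 0.21. Camera called interferon-stimulated genes (adjusted p = 0.0252), and with an estimated correlation the adjusted p was 0.773 for the endothelial, smooth muscle and interferon-stimulated lists. Of 20 muscle atrophy genes 10 fell and 2 rose, and 12 and 2 adjusted over the list alone, UBB at -1.37 ± 0.14. Camera called muscle atrophy genes (adjusted p = 0.0308, 0.108 after quantile normalization, 0.0528 without DE29, adjusted p = 0.773 with an estimated correlation). Of 66 ribosomal protein genes 22 fell and 3 rose, and 18 and 2 adjusted over the list alone, RPL30 at -1.17 ± 0.14. Camera called ribosomal protein genes (adjusted p = 0.0302, 0.388 after quantile normalization, 0.117 with the slide and 0.0802 with the slide set as a block, 0.0683, 0.0721 and 0.0628 without K3, K9 and DE32, adjusted p = 0.844 with an estimated correlation).

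**Figure D4:**
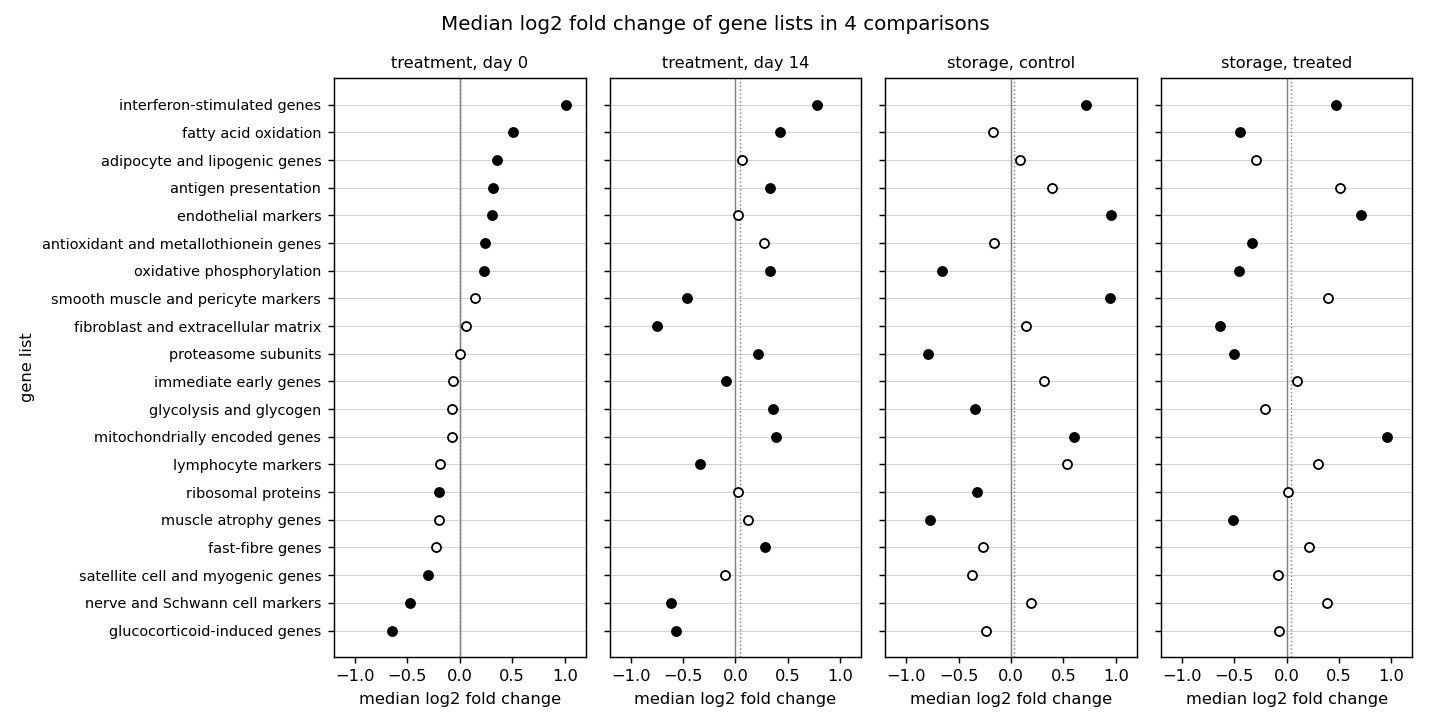
Median log2 fold change of 20 gene lists in 4 comparisons; filled points passed camera at an adjusted p under 0.05 with the preset correlation, open points did not, and the dotted line is the median of all genes. With an estimated correlation only fatty acid oxidation at day 0 passed, at 0.0273.

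Limma called 4873 probes (3437 genes) higher and 3562 (3042 genes) lower at day 14 over all animals, 54.6% of those tested, and 2278 probes with the slide as a block. The count of each direction depended on the scaling, because the median log2 fold change over all probes was 0.11 with the main values, -0.21 with median centring, -0.02 after quantile normalization, -0.02 in the series table and 0.48 after normexp correction. The called probes were 57.8% higher with the main values, 31.6% with median centring (2737 higher, 5913 lower), 47.7% after quantile normalization (3770 and 4138), 47.4% in the series table (3677 and 4085) and 75.9% after normexp correction (8226 and 2619). In control animals the share was 55.7%, 29.5% with median centring and 77.1% after normexp correction, and in treated animals 61.1%, 29.5%, 80.9% and, after quantile normalization, 45.6%. The median of each list called for storage had the same sign under each of these scalings. Within scan sessions 1, 2 and 3, 99.4%, 100% and 93.9% of the called probes kept their sign, and in slide sets 1 and 2 99.6% and 98.6%. Medians in the called direction were 0.83, 0.82, 0.66, 0.83 and 0.72 against 0.80 over all arrays.

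Control and treated animals shared 1929 probes called higher and 1495 called lower with storage, where independent lists would share 612 and 309, and 0 probes were called in opposite directions. The log2 fold changes correlated across probes with Pearson's r = 0.845 and Spearman's rho = 0.844. Whether storage acted differently in treated muscle was tested directly, and limma called 0 probes, with 541 at an unadjusted p under 0.05 where chance gives 772 and a smallest adjusted p of 1. The genes with the smallest p were MB, the oxygen carrier myoglobin (1.28 ± 0.26, n = 5 per group), UBA1 (1.27 ± 0.32) and MYO16 (1.75 ± 0.45) in one direction and the matrix protein TNC (-2.29 ± 0.69), GEM (-1.14 ± 0.34) and GABRA3 (-1.44 ± 0.43) in the other, and none passed.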

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

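Each test in this part was chosen before its result was seen, except the slide and slide set blocks of the gene lists. Single arrays that stood apart from the other arrays of their group were looked for in 68 groups of 5 values, the array measures and the plotted genes, and 7 were found where chance gives about 1 in 20, or 3.4. FKBP5 was 4.969 (log2 signal) in treated animal DE27 at day 0 against 8.554 to 8.859 in the other treated animals. CAST was 12.38 in control animal K8 at day 0 against 11.60 to 11.80 in the other controls, and 11.67 in control animal K10 at day 14 against 10.75 to 11.01. IFIT3 was 3.485 in control animal K6 at day 14 against 1.883 to 2.310 in the other controls, all 5 values not well above background. GLRX2 was 7.932 in treated animal DE30 at day 14 against 7.189 to 7.361 in the other treated animals. Outlier spots numbered 108 on the day 14 array of K6 against 23 to 38 in the other controls, and 176 on the day 14 array of DE27 against 6 to 38 in the other treated animals.

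In 10 gene lists the change with storage differed between treated and control animals by camera's test of the interaction, although no gene passed in any of them, fry called 0 lists and with an estimated correlation 0 were called (adjusted p from 0.583 to 0.839). Fibroblast and extracellular matrix genes changed more towards lower values in treated animals (32 of 33 genes, median -0.81, adjusted p = 4.21e-13), as did smooth muscle and pericyte markers (median -0.54, adjusted p = 6.26e-05). Ribosomal protein genes went the other way (59 of 66 genes, median 0.25, adjusted p = 2.67e-07). These 3 lists kept their call without each animal in turn, after quantile normalization and normexp correction, and with the slide or the slide set as a block. However, the fibroblast median for treatment at day 14 was -2.22 in scan session 1, which holds 1 control array at that day (K6), and -0.02 in session 2. For storage in treated animals it was -1.52 and 0.04 in these sessions, with 1 day 0 array in session 1. The smooth muscle median for treatment at day 14 was -1.40 and -0.16 in them, and 1.17 in slide 5. The interaction itself was not split by session. Fast-fibre genes (median 0.74, adjusted p = 0.000315) and adipocyte and lipogenic genes (median -0.36, adjusted p = 0.00662) were not called without DE31 (0.0641 and 0.089). Proteasome subunits (0.19, adjusted p = 0.00587) were not called without K9, DE27 and DE30 (0.135, 0.371 and 0.0985). Macrophage and myeloid markers (-0.37, adjusted p = 0.0127, median 0.01 after normexp correction) were not called without K6, K9, DE27 and DE30 (0.555, 0.378, 0.371 and 0.13). Mitochondrially encoded genes (0.35, adjusted p = 0.0164) were not called without K3, K10, DE31 and DE32 (0.203, 0.0557, 0.0641 and 0.103). Glycolysis and glycogen genes (0.41, adjusted p = 0.0232) were not called without K9, DE27, DE30 and DE31 (0.35, 0.105, 0.323 and 0.0641). Endothelial markers (-0.24, adjusted p = 0.0295) were not called without K3, K8, K9, DE27, DE30 and DE31 (0.0526, 0.066, 0.47, 0.347, 0.13 and 0.171). These last 4 lists and the proteasome list also lost their call under another scaling or with a slide block, with adjusted p of 0.077 for proteasome subunits and 0.28 for macrophage markers after normexp correction. After quantile normalization it was 0.842 for mitochondrially encoded genes, 0.301 for glycolysis genes and 0.0753 for endothelial markers.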

How the results depend on the processing

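The slide set and scan session blocks, the array median in the fit, the animal as a replicate block with the slide set, the random animal block added to the slide block over both days, and the slide and slide set blocks of gene lists were chosen after seeing the data. All other alternatives were chosen before. Treatment at day 0 (378 probes called) gave 231 without a filter, 699 with array weights, 839 at a threshold of 0.1 and 203 with all arrays and the animal as a random replicate block. Treatment at day 14 (11) gave 1 after normexp correction, 7 with probes above background on all arrays, 0 with the slide as a block, 20 with array weights, 20 with an intensity trend, 28 at a threshold of 0.1, 110 with the random replicate block, 3 with the scan session as a block and 18 with the array median relative to the 75th percentile in the fit. Treatment over both days (511) gave 133 after normexp correction, 1052 at a threshold of 0.1, 932 with the random replicate block, 935 with the slide set and 1049 with the scan session as a block. Storage gave, in control animals (6045), 183 with the slide as a block and 0 with the animal as a replicate block together with the slide set (3477 at an unadjusted p under 0.05 in limma). In treated animals (4586) it gave 8813 after normexp correction, 8723 without a filter and 0 with the slide as a block (3042 at an unadjusted p under 0.05), and in all animals (8435) 13305 without a filter and 2278 with the slide as a block. The cause was not tested, except that the looser threshold and the missing filter change the tests counted. The interaction gave 0 under each alternative run.

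Leaving out 1 animal in turn gave 135 to 312 probes for treatment at day 0, 0 to 12 at day 14 (12 without K6, 10 without DE31, 8 without DE32), 215 to 535 over both days, 3214 to 6655 for storage in control animals, 2441 to 5703 in treated animals and 7448 to 9063 in all animals, 0 to 9 probes shared between the treatment effects of the days, and 6 to 14 lists for the interaction. With the animal as a replicate block, which pairs the arrays of an animal, storage called 5501 probes in control, 4000 in treated and 8304 in all animals, and in treated animals the calls of CAST, MMP2, GBP4, IFI35, ETFA and HADH ended (adjusted p = 0.0598, 0.0899, 0.0711, 0.078, 0.057 and 0.0707). The animal replicate block changed no other call of a named gene and, for the interaction, called 0 probes as well (582 at an unadjusted p under 0.05).

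Camera called 11, 14, 10, 9, 9, 8 and 10 lists in the treatment comparisons (day 0, day 14, both days), the storage comparisons (control, treated, all animals) and the interaction. With an estimated correlation it called 1, 0, 0, 0, 0, 0 and 0. Fry called 0 for treatment at day 14, 2 over both days, 1 for storage in treated animals, 16 in all animals and 0 for the interaction. For storage, 16 lists were called in control animals after normexp correction. With the slide as a block the days of treated animals are compared through DE32 alone, so that count of lists is left out. No list was called in the opposite direction under any alternative run.

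Over all named genes and alternatives, treatment at day 0 kept 1540 of 1757 results on their side of the threshold with 0 reversed, day 14 kept 1664 of 1781 and both days 1441 of 1642, also with 0 reversed. Storage kept 1102 of 1255 in control, 1086 of 1256 in treated and 1439 of 1495 in all animals. Normexp correction reversed EHHADH (0.0283), GYG2 (0.363), PRKCQ (0.363) and PSMB1 (0.802) in control animals, BRMS1L (0.334), EPDR1 (0.41), EHHADH (0.576) and FBXO31 (1.01) in treated animals, and EHHADH (0.302), BRMS1L (0.177), EPDR1 (0.172) and GYG2 (0.633) in all animals. MMP2 reversed in treated animals with the slide as a block (0.293), which compares the days through DE32 alone. CTSD reversed with median centring (-0.059) and GAPDH after quantile normalization (-0.354) in all animals. Median centring moved the median of all probes from 0.105 to -0.207, which by itself takes CTSD below 0, and normexp correction moved it to 0.476. Of the probes called over all animals, 74.7% were called in the same direction with median centring and 77.4% after normexp correction, with 526 called in the opposite direction after the latter. Signal over background limits which probes were tested, with 6037 left out and 62.2% and 61.9% of spots above it in the day 14 groups, but whether dim probes account for the changed calls was not tested.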

Other observations

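The tests of the slide set, the normalization and the slide for storage, those of the matching of arrays and the batches and array measures of the day 14 split were chosen after the result was seen. Clock genes other than PER1 moved in treated muscle too, and the genes in this paragraph and the next were chosen after their values were seen. Over both days BHLHE40, a transcriptional repressor of the clock, rose by 1.46 ± 0.21 (log2, n = 5 per group, adjusted p = 0.00596), while TEF, an output gene of the clock, fell by 0.81 ± 0.14 (adjusted p = 0.0142), PER2 fell by 1.32 ± 0.31 (adjusted p = 0.0429) and WEE1 fell by 0.59 ± 0.14 (adjusted p = 0.0461). ARNTL, which drives PER1 and PER2, had 0.79 ± 0.23 (adjusted p = 0.0838, 0.0128 adjusted over the list alone). Of 19 clock genes, 1 rose and 4 fell over all probes, and 3 and 5 adjusted over the list alone. Camera did not call the list (adjusted p = 0.2, fry 0.099), although fry called it as lower at day 0 (0.0411). GREB1, an oestrogen-induced gene, rose by 1.29 ± 0.28 (adjusted p = 0.0354), the only member of the oestrogen-responsive list that rose over all probes (1 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.982).

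With storage in all animals, muscle calpain CAPN3 fell by 1.63 ± 0.27 (log2, n = 10 per day) and the initiator caspase CASP8 rose by 1.55 ± 0.30, and of 17 calpains, cathepsins and caspases 3 rose and 2 fell by either count. The mitochondrial chaperone HSPA9 fell by 1.23 ± 0.18, and 12 of 28 heat shock genes fell and 2 rose by either count. Of 19 genes commonly used as references 8 fell and 2 rose by either count, among them HPRT1 (-2.02 ± 0.37), PGK1 (-1.51 ± 0.22) and POLR2A (1.05 ± 0.21), while 54.6% of all probes were called. The globin gene HBA rose by 2.01 ± 0.66 and the haem enzyme ALAS2 by 1.12 ± 0.37, with 5 of 6 erythroid genes that rose over all probes and 6 adjusted over the list alone. Camera called none of these lists (adjusted p of 0.884, 0.24, 0.133 and 0.0891), while fry called the reference genes as lower (0.00592) and the erythroid genes as higher (0.000676). Lists that camera called in no comparison had smallest adjusted p of 0.188 for apoptosis, 0.076 for calpains, cathepsins and caspases, 0.186 for clock, 0.0686 for erythroid, 0.501 for growth signalling, 0.144 for heat shock, 0.304 for hypoxia, 0.0829 for inflammatory, 0.0861 for oestrogen-responsive, 0.0751 for proliferation, 0.13 for reference, 0.407 for slow-fibre and 0.424 for steroid receptor and steroid metabolism genes.

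Chance was tested with 100 splits of the same animals or arrays, the real one included. Treatment at day 0 called 378 probes and at most 2 in any other split, and over both days 511 and at most 3, so that only 1 split, the real one, was as large. This share of 0.01 is the smallest that 100 splits can give, so it argues against chance for both without excluding it. At day 14, 2 of 100 splits called 11 probes or more, the real one included, which met the bound set in advance. However, 1 other split called 56 probes, more than the real one, so that chance stays open for the 11 probes. Whether a structure of the samples beyond the treatment lies behind this other split was looked at after the split was seen. That split (K3, K6, K9, DE29 and DE32 against the others) followed neither the slide set, with 3 and 4 arrays of set 2 on its sides, nor the scan session, with 2 and 3 of session 2. Of 5 array measures compared between its sides, none passed, and the smallest exact permutation p was 0.0159 (adjusted p = 0.0795), for the median signal relative to the 75th percentile (-2.877 and -3.012). With this median in the fit the split called 0 probes (694 at an unadjusted p under 0.05 in limma) and treatment 18. With the 75th percentile in the fit they called 2 and 5. With the shares of spots well above background and found, and with outlier spots, the split called 37, 75 and 64. Its sides hardly overlap in the median, so the fit cannot tell the split from this measure, and what parts its sides stays open. Storage called 6045 probes in control animals (highest other 577), 4586 in treated animals (highest other 141) and 8435 in all animals (highest other 6609, a split that exchanged the days of 1 animal). In each, only the real split of the 100 was as large, which argues against chance. Of the 16 splits of a treatment's arrays that part every pair, the highest others were 577 and 709. For the interaction the splits say nothing about chance, because with a real count of 0 each of the 100 splits is as large (highest other 10).

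Of 26 genes that glucocorticoids induce, 5 fell and 1 rose over all probes at day 0 in animals that had been given one, and the list was called with a preset correlation but not with an estimated one (adjusted p = 0.204). The mean of the list was -0.65, and it was -0.718 with the slide as a block, -0.544 after normexp background correction, the normalization alternative nearest to 0, and -0.557 without the animal that mattered most, all beyond the bound of -0.3 set in advance, which argues against slide, normalization or 1 animal as the whole cause. It was -0.56 without PER1 and -0.51 at day 14. The treatment stays open as the explanation that the design names, and how it would lower these genes was not tested.

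Probes that differed between storage days were weighed against slides and scaling. With the slide set as a block 89.1% of the 8435 probes were called in the same direction, and after quantile normalization 82.2%, both above the bound of 75%, which argues against the slide set and against distortion by brightness as the whole cause. With the slide as a block only 25.8% were, under the bound of 50%, which by the bound alone goes with the slide as the cause. Only 2 of the 6 slides hold both days, and the median SE went from 0.17 to 0.31. With that block 98.3% of the 8435 probes kept their sign, with a median in the called direction of 0.69 against 0.80. Within slides 5 and 6, the slides that hold both days, 95.8% and 93.9% kept it, with medians of 0.74 and 0.66. That the bound does not decide with so few shared slides was settled after the 25.8% was seen. The kept sign and size argue against the slide as the whole cause for these probes as a set, although the probes were chosen over the same arrays. For single probes that lost their call, slide and storage cannot be told apart. Loss of RNA during storage, which the lower array signal could reflect, was not tested, and no biological explanation apart from storage itself was tested.

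The day 14 arrays of control animals K8, K9 and K10 may not come from the animals their numbers name. This was noticed in these data and then tested on them, after trying several settings. Values were first adjusted for treatment and slide set within each day. The test used 19 probes whose adjusted day 0 values split the animals by a gap of at least 1.5 log2 with at least 2 animals on each side. Of 120 ways to match control arrays across days, 11 matched as well as the labels (mean r 0.339), and the best (0.834) paired day 0 of K8, K9 and K10 with day 14 of K10, K8 and K9. For treated arrays, where 3 of 5 animals change slide set as in controls, only 1 way, that of the labels, matched as well (0.709), which argues against the slide set as the cause. Without KCNK15, the only one of these probes called between slide sets, the counts were again 11 and 1. Because the values were already adjusted for the slide set, leaving this probe out says little about it. A mislabelled sample is a candidate explanation, but with a gap of 2 and 8 probes 6 ways matched as well as the labels, which lies on the other side of the bound, although the best way was the same (mean r 0.833 against 0.469). Group comparisons do not depend on these numbers, but fits with the animal as a block, animal means and left-out animals do.

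Between slide sets 963 probes differed, 494 higher and 469 lower in set 2, of which 429 were also called for storage and 5 for treatment at day 0. The largest differences were in KCNK15 (6.70 ± 0.62) and KLK9 (6.53 ± 0.41). Set 1 holds 4 of 5 control arrays at day 0 and 1 of 5 at day 14, and of the treated arrays 3 and 2.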
